A study of Mus musculus with 3 samples.

How the data were processed

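Single-nucleus RNA sequencing was done on DAPI-stained, sorted nuclei from mouse cerebral cortex, with 1 library per genotype. The genotypes, per the labels, were a control (CTRL), a heterozygous Eed deletion (Eed-cHet) and a homozygous Eed deletion (Eed-cKO). Eed encodes a core subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine 27 and keeps developmental genes silent. The deletion was driven by Emx1-iCre, a Cre recombinase active in the dorsal telencephalon. Excitatory neurons, astrocytes and part of the oligodendrocytes of the cortex arise there, while cortical inhibitory neurons and microglia arise elsewhere.

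The deposited matrices hold UMI counts (unique molecular identifiers, whole-number counts) per gene and nucleus barcode, made by the authors with the 10x Genomics 3′ kit version 3.1 and Cell Ranger. The submitters' notes give Cell Ranger 7.0.1, Seurat and genome mm10, while the matrix headers give cellranger 6.0.1. Whether intronic reads were counted, and whether any nuclei were removed before deposition, is not stated.

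The matrices list 32285 features, of which 32235 matched the GENCODE M21 annotation by Ensembl ID. Nuclei with fewer than 500 genes or more than 5% mitochondrial UMIs were left out. That removed 114 CTRL, 136 Eed-cHet and 109 Eed-cKO nuclei. Scrublet, run on each library in scanpy 1.11.5, called 23, 83 and 43 of the remaining nuclei doublets, and these were left out too. The nuclei used numbered 2731, 4719 and 4309.

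The nuclei of the 3 libraries were clustered together with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9 and scikit-learn 1.9.0 under python 3.11.15. The steps were total-count scaling, log transformation, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, with no integration and seed 0. Clusters were named from fixed marker lists, using genes detected in at least 10% of a cluster's nuclei. Excitatory nuclei were then clustered again alone and named with subclass markers. A class name means that the nuclei are like that cell type in these markers.

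For each class and library the UMIs of all nuclei were summed and scaled to the total of that class and library as CPM. CPM carry exact Poisson 95% intervals, shares carry exact Clopper-Pearson 95% intervals, and ratios carry exact conditional (binomial) 95% intervals. All of these cover counting error only. With 1 library per genotype no test between genotypes could be run, and no p-value, standard error or count of changed genes is given. No replicate shows how far 2 mice of 1 genotype differ. Where a share or a level rests on 0 counts, the limit printed is 3 counts of the total and not the interval's upper bound. A ratio against 0 counts is given as a lower bound, with 3 counts over the class in that library as the floor. Ratios were computed with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

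Gene groups were read through 22 fixed lists. They were the Hox clusters, transcription factors of other brain regions, ventral telencephalic transcription factors, transcription factors of non-neural tissues, cyclin-dependent kinase inhibitors, PRC2 subunits, PRC1 subunits, H3K27 demethylases and acetyltransferases, upper-layer identity genes, deep-layer identity genes, cortical area patterning genes, cell cycle genes, immature neuron genes, synaptic and mature neuron genes, immediate early genes, Wnt and BMP signalling genes, beta protocadherins, p53 targets, imprinted genes, housekeeping genes, sex-linked genes, and stress and dissociation genes. A member was measured in a comparison when it had at least 30 UMIs over the 2 libraries. A list's value is the median log2 ratio of its measured members with a prior of 0.5 counts. Its interval comes from 1000 Poisson draws of the counts. The median is also placed among 10000 random lists of the same size, matched on expression in 20 bins, which describes these libraries and is not a test. Members at least 1.5-fold higher or lower were counted by size alone.

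For shares of nuclei with a UMI of a gene, each nucleus was thinned to 1500 UMIs and shallower nuclei were left out. Gene comparisons were made in the 6 classes with at least 50 nuclei in each library.

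The lists, the settings, the comparisons and the rule for named genes were fixed before the data were examined. Under that rule, named genes needed at least 30 UMIs over the 2 libraries and were outside the mitochondrial, ribosomal protein, haemoglobin and sex-linked groups. In excitatory neurons of Eed-cKO against CTRL they were the 15 highest ratios, ranked by the lower interval bound, and the 10 lowest, ranked by the upper bound, among genes that also lay at least 1.5-fold from Eed-cHet the same way. In excitatory neurons of Eed-cHet against CTRL, and in inhibitory neurons of Eed-cKO against CTRL, they were the 5 highest and 5 lowest. In each other class of Eed-cKO against CTRL they were the 3 highest and 3 lowest. The condition on Eed-cHet held in every class for Eed-cKO. In each list, examples were taken from the 2 highest and 2 lowest measured members, and Eed, Ezh2, Suz12, Cdkn2a and the sex-linked genes were named in any case. Other genes named were chosen after their values were seen.

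The procedure was tested on simulated counts for 16095 genes. The 95% interval held 96.0% of the true ratios. The counts were independent Poisson draws, the model that the intervals assume, with no spread between nuclei or mice. Coverage near 95% was therefore fixed in advance and says nothing of real spread. Among genes raised 2-fold, 93% ranked in the top 200 by lower bound, with a median estimate of 1.96, and among genes raised 4-fold, 100% did, with a median of 3.97. As many genes were raised as the 200 ranks scored. All of them were well counted, so genes with few UMIs in CTRL were not covered.

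Alternatives tried were doublets kept, no filter on nuclei, at least 1000 genes per nucleus, Leiden resolutions 0.5 and 2, each library clustered alone, values centred within each library, the fixed lists left out of the variable genes, median-of-ratios scaling, minimums of 10 and 100 UMIs, a prior of 2 counts, thinned nuclei, a mean over nuclei, a fixed subclass composition and Eed-cHet as the reference. Another 3 were chosen after seeing the data: excitatory nuclei with no UMI of Gad1, Gad2 or Slc32a1, excitatory nuclei without joint cluster 19, and joint cluster 4 alone. Median-of-ratios scaling over 12437 genes placed the median gene of excitatory neurons 0.10 higher on the log2 scale in Eed-cKO than in CTRL under the total-count scaling used. The shift was under 0.1 in every other comparison with CTRL.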

Results

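RNA was counted in single nuclei from the cortex of CTRL, Eed-cHet and Eed-cKO mice, and each genotype is 1 library. The CTRL library held 2868 barcodes and 15268972 UMIs, the Eed-cHet library 4938 barcodes and 28204516 UMIs, and the Eed-cKO library 4461 barcodes and 23807852 UMIs. Depth per nucleus was alike, with medians of 3451.5, 3358 and 3526 UMIs and of 1657, 1621.5 and 1711 genes in that order. The design asks how cells of the dorsal telencephalon differ when 1 or both copies of the PRC2 gene Eed are deleted.

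The targeted gene, Eed (ENSMUSG00000030619, chromosome 7, 89954654 to 89980983 in GRCm38/mm10), had like levels in excitatory neurons of the 3 libraries. It stood at 23.5 CPM (20.8 to 26.5) in CTRL, 24.8 CPM in Eed-cHet and 23.9 CPM (21.3 to 26.7) in Eed-cKO, a ratio of 1.01 (0.858 to 1.20) between Eed-cKO and CTRL. Inhibitory neurons had 26.1, 33.1 and 23.2 CPM, astrocytes 30.5, 32.9 and 37.1 CPM, and microglia 151, 126 and 172 CPM. Oligodendrocytes had 47.0, 49.0 and 49.4 CPM, and oligodendrocyte precursors 56.0, 38.1 and 35.1 CPM. The kit reads the 3′ end of a transcript, which can lie outside the deleted part, so these levels check neither the genotype nor the deletion. Eed overlaps E230029C05Rik and Gm45120 in the annotation. The other PRC2 core genes in excitatory neurons were Ezh2, the methyltransferase gene, at 19.6 CPM in CTRL and 23.5 CPM in Eed-cKO (ratio 1.20, 1.00 to 1.43), and Suz12 at 50.2 and 59.4 CPM (ratio 1.18, 1.06 to 1.32). Xist, the RNA of the inactive X chromosome, was at 1683, 1847 and 1800 CPM in excitatory neurons, and the Y-linked gene Uty had 2, 5 and 4 UMIs there, as in female mice.

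In the joint clustering, excitatory neurons made up a smaller share of nuclei in Eed-cKO and inhibitory neurons a larger one than in CTRL. Excitatory neuron-like nuclei, called excitatory neurons below, were 50.5% (48.6 to 52.4) of nuclei in CTRL, 40.2% (38.8 to 41.6) in Eed-cHet and 36.9% (35.5 to 38.4) in Eed-cKO. With each library clustered alone, the excitatory shares were 36.6%, 30.8% and 36.8%, but clusters left unnamed that scored highest for excitatory neurons held 383 CTRL, 461 Eed-cHet and 0 Eed-cKO nuclei. With those added, a step chosen after seeing the data, the shares were 50.6%, 40.6% and 36.8%. Inhibitory neurons were 8.57% (7.55 to 9.68), 7.20% (6.48 to 7.98) and 13.3% (12.3 to 14.4). Nuclei with the markers of striatal projection neurons were 11.9% (10.9 to 12.9) of the Eed-cKO library, with 512 nuclei, against 1 nucleus in CTRL and 2 in Eed-cHet. The share was 6.76% with doublets kept, 6.63% with no filter on nuclei and 6.82% at resolution 2. Without these nuclei the excitatory share of Eed-cKO was 41.9% and the inhibitory share 15.1%. Among excitatory and inhibitory neurons alone, inhibitory neurons were 14.5% in CTRL, 15.2% in Eed-cHet and 26.5% (24.7 to 28.4) in Eed-cKO.

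Glial shares also differed between the libraries. Oligodendrocytes were 17.1% (15.7 to 18.6) of nuclei in CTRL, 23.3% (22.1 to 24.6) in Eed-cHet and 11.6% (10.6 to 12.6) in Eed-cKO. Astrocytes were 5.35% (4.53 to 6.26), 9.81% (8.98 to 10.7) and 9.05% (8.21 to 9.95). Microglia or macrophages were 13.1%, 13.3% and 10.2%, oligodendrocyte precursors 3.37%, 3.37% and 4.15%, and fibroblasts 1.79%, 1.89% and 2.18%. Endothelial cells gave 4, 11 and 1 nuclei. Pericytes gave 4 nuclei in Eed-cHet, 6 in Eed-cKO and 0 in CTRL, which allows a share of up to 0.110%. The piece of tissue taken sets these shares too, and only 1 library per genotype was sequenced.

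**Figure D1:**
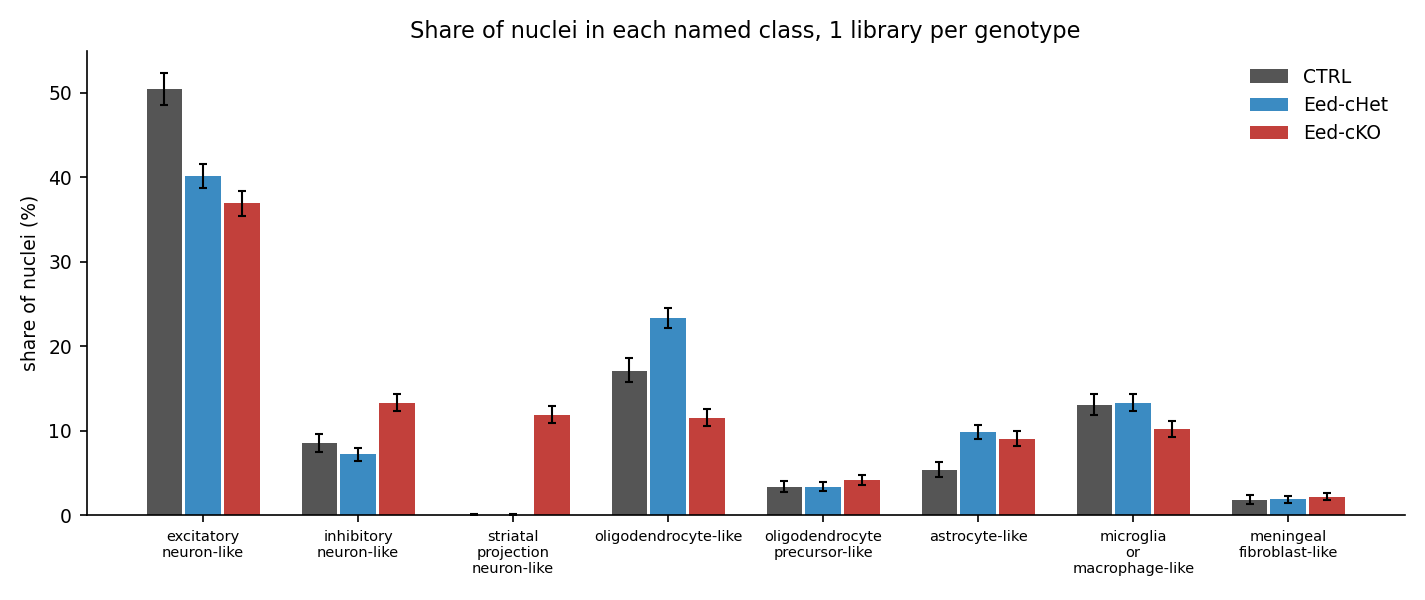
Share of nuclei (percent) in each cell class for the CTRL, Eed-cHet and Eed-cKO libraries, with exact 95% binomial intervals. Striatal projection neuron-like nuclei reach 11.9% in Eed-cKO, and excitatory neurons are 50.5% in CTRL and 36.9% in Eed-cKO.

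The main comparison asks which genes differ in excitatory neurons, the neurons of the Cre lineage, between Eed-cKO and CTRL. Hox genes, which set position along the trunk and are silent in the forebrain, were present in Eed-cKO and not detected in CTRL. Their summed level was 112 CPM in Eed-cKO against 0 UMIs in CTRL and 1 UMI in Eed-cHet. Transcription factors of other brain regions and of non-neural tissues, such as Foxd1, Tal1 and Twist1, were higher by medians of 6.16 and 4.61 on the log2 scale. Deep-layer genes such as Foxp2 were higher (median log2 ratio 1.11), and upper-layer genes such as Cux2 were lower (-0.83).

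Of the 39 genes of the Hox list, 15 were measured. CTRL had no Hox UMI, so each passed the minimum of 30 UMIs through Eed-cKO and could only be higher there. Their median log2 ratio was 6.77 (6.50 to 6.96), or 4.18 with the genes at 0 set to the floor. Hoxd11 (ENSMUSG00000042499, chromosome 2, 74679557 to 74687016) was at 0 in CTRL and 19.3 CPM (16.9 to 21.8) in Eed-cKO, at least 72.0-fold higher. Hoxc4 (chromosome 15, 103018934 to 103036852) was at 14.4 CPM, at least 53.9-fold higher, and Hoxc6 (chromosome 15, 102998257 to 103011881) at 14.3 CPM, at least 53.4-fold higher. Hoxd10 was at 6.75 CPM, Hoxa7 at 4.83 CPM, Hoxb6 at 3.37 CPM and Hoxa3 at 2.38 CPM, so all 4 Hox clusters were represented. Hoxc5, at 4.83 CPM, Hoxc6 and Hoxa3 overlap neighbouring Hox genes in the annotation, so the gene behind each of their UMIs is uncertain.

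In nuclei thinned to 1500 UMIs, 208 of 1537 excitatory nuclei of Eed-cKO, or 13.5% (11.9 to 15.4), had a Hox UMI, with 53 shallower nuclei left out. Unthinned, the share was 29.2%. In CTRL it was 0 of 1335 thinned nuclei, with 43 left out, which allows a share of up to 0.225%, and in Eed-cHet 1 of 1847, with 48 left out. Microglia, which lie outside the Cre lineage, had a Hox UMI in 1.45% of thinned Eed-cKO nuclei and 1.37% unthinned, with 231 left out. In CTRL and Eed-cHet microglia it was 0.680% and 1.08% thinned, with 210 and 257 left out, and 1.12% and 1.75% unthinned, so Eed-cKO did not stand apart in that class. Median depth of Eed-cKO microglia was 1465 UMIs, against 6870.5 in the excitatory neurons of that library. Inhibitory neurons of Eed-cKO had 1 of 529 thinned nuclei with a Hox UMI, with 45 left out, at a median depth of 4740.5 UMIs. Astrocytes, which the Emx1 lineage also forms, had 4 of 307 (1.30%), with 83 left out, at a median depth of 2402.5 UMIs.

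**Figure D2:**
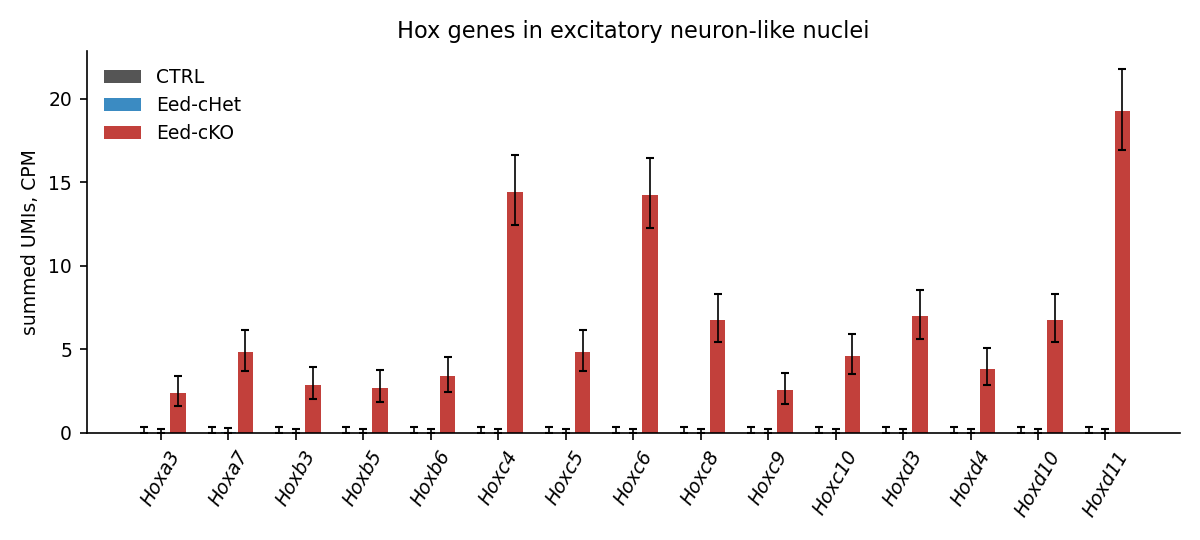
Levels (CPM) of single Hox genes in excitatory neurons of the CTRL, Eed-cHet and Eed-cKO libraries, with exact Poisson 95% intervals. Genes drawn had at least 30 UMIs over CTRL and Eed-cKO. Summed over the Hox genes, which is not drawn, excitatory neurons of Eed-cKO stand at 112 CPM and astrocytes of Eed-cKO at 12.4 CPM.

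Transcription factors of other brain regions were at 2.05 CPM in sum in CTRL and 99.7 CPM in Eed-cKO. With 23 UMIs over the whole list in CTRL, its members too could reach the minimum of 30 UMIs only with UMIs from Eed-cKO, which nearly fixes their direction. Of that list of 51, 15 were measured, and all were higher (median log2 ratio 6.16, 5.85 to 6.45; 4.28 with zeros at the floor). Tal1, a factor of midbrain and spinal interneurons and of blood, had 1 UMI in CTRL and 162 in Eed-cKO, a ratio of 139 (24.7 to 5541). Pax2, of the midbrain-hindbrain border, was at 0 in CTRL and 7.44 CPM in Eed-cKO, at least 27.8-fold higher. Gata3, with 3 UMIs in CTRL, had a ratio of 17.8 (5.81 to 88.6), and Dbx2, a spinal progenitor factor, a ratio of 19.4 from 2 UMIs in CTRL. Onecut1, a factor of spinal and retinal neurons and liver, had 1 UMI in CTRL and stood at 18.6 CPM in Eed-cKO (ratio 209, 37.2 to 8295).

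All 14 measured members of the 53 transcription factors of non-neural tissues were higher too (median log2 ratio 4.61, 4.11 to 6.09; 3.85 with zeros at the floor). No member had more than the 23 UMIs of Twist2 in CTRL, so each reached the minimum of 30 UMIs only with UMIs from Eed-cKO, which favours higher values. Over the whole list, with no minimum, the sum was 8.02 CPM in CTRL and 126 CPM in Eed-cKO. Foxd1 (ENSMUSG00000078302, chromosome 13, 98354242 to 98359305), a factor of kidney stroma and the optic region, was at 0 in CTRL and 24.2 CPM (21.6 to 27.1) in Eed-cKO, at least 90.7-fold higher. Twist1, of mesoderm and neural crest, was at 13.7 CPM, at least 51.4-fold higher, and Tbx20, a heart factor, at 12.2 CPM, at least 45.6-fold higher. Tbx15 (ratio 6.57, 3.49 to 13.7) and Twist2 (2.17, 1.32 to 3.69) were the members with the lowest ratios by upper bound. The lincRNA 1700018A04Rik (chromosome 13, 31565492 to 31625792) was at 0 in CTRL and 23.0 CPM in Eed-cKO, at least 86.1-fold higher.

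Genes of the ventral telencephalon, the source of striatal and inhibitory neurons, were higher in excitatory neurons of Eed-cKO. Of 20 listed, 7 were measured, 5 were higher and none was lower (median log2 ratio 4.57, 3.09 to 6.09; 5.08 with zeros at the floor). Isl1, with 0 UMIs in CTRL, and Ebf1, with 15, passed the minimum of 30 UMIs only with UMIs from Eed-cKO, which favours higher values. Ebf1 (ENSMUSG00000057098, chromosome 11, 44617317 to 45008091), a factor of striatal neurons, was at 1.34 CPM in CTRL and 74.9 CPM in Eed-cKO, a ratio of 56.1 (33.8 to 101). Isl1, of striatal and motor neurons, was at 0 and 9.05 CPM, at least 33.9-fold higher. Maf (ratio 0.857, 0.713 to 1.03) was near CTRL. The GABA synthesis genes Gad1 and Gad2 and the GABA transporter gene Slc32a1, chosen after their values were seen, were at 0.713, 0.980 and 1.43 CPM in CTRL. In Eed-cKO they were at 29.8, 32.7 and 16.5 CPM, ratios of 41.7, 33.3 and 11.6. Slc17a7, the glutamate transporter gene of cortical excitatory neurons, was at 203 CPM in CTRL and 177 CPM in Eed-cKO.

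Other genes with high ratios were Dach1 (ENSMUSG00000055639, chromosome 14, 97786853 to 98169765), a transcriptional cofactor, at 4.54 CPM in CTRL and 264 CPM in Eed-cKO (ratio 58.1, 44.1 to 78.2). Zfhx3, a homeobox factor of maturing neurons, was at 4.63 and 174 CPM (37.5, 28.5 to 50.4), and Kcnmb2, a potassium channel subunit gene that also marks inhibitory neurons, at 2.58 and 101 CPM (39.2, 27.2 to 58.8). E130114P18Rik was at 1.87 and 87.5 CPM (46.8, 30.4 to 75.8), but it overlaps Nfia, so the source of its UMIs is uncertain. Vax2os, antisense to the eye factor gene Vax2, was at 0 and 10.7 CPM, at least 40.2-fold higher.

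Upper-layer identity genes were lower in Eed-cKO, with 10 of 14 measured members at least 1.5-fold lower and 2 higher (median log2 ratio -0.83, -0.97 to -0.69). In joint cluster 4 alone the median was 0.69, with 0 of 11 members lower. Over all excitatory nuclei the median was below that of all 10000 random lists. Lamp5, a membrane protein gene of upper-layer neurons, was at 69.9 CPM in CTRL and 16.2 CPM in Eed-cKO (ratio 0.232, 0.198 to 0.270). Cux2 (ENSMUSG00000042589, chromosome 5, 121856366 to 122050102), the classic upper-layer homeobox gene, was at 199 and 49.6 CPM (0.249, 0.228 to 0.272). Cux1 had a ratio of 0.366 and Rorb, of layer 4, a ratio of 0.409. Mdga1 (1.83, 1.55 to 2.16) and Inhba (1.55, 1.39 to 1.74) were higher.

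Deep-layer identity genes were higher, with 13 of 16 measured members at least 1.5-fold higher and none lower (median log2 ratio 1.11, 1.02 to 1.16). In joint cluster 4 alone the median was -0.43, with 2 of 16 members higher. Foxp2 (ENSMUSG00000029563, chromosome 6, 14901349 to 15441977), of layer 6 and also of striatal neurons, was at 27.7 CPM in CTRL, 43.3 CPM in Eed-cHet and 270 CPM in Eed-cKO (ratio 9.73, 8.67 to 11.0). Rprm, a cell cycle arrest gene of layer 6, was at 1.34 and 12.7 CPM (9.53, 5.61 to 17.4). Bcl11b, of subcerebral and striatal neurons, had a ratio of 4.67, and Fezf2, which specifies subcerebral neurons, a ratio of 3.01. Tbr1 (0.866, 0.696 to 1.08), the layer 6 master factor, and Ntng2 (1.15, 0.982 to 1.34) were near CTRL. After thinning, a Foxp2 UMI was in 28.4% of Eed-cKO excitatory nuclei and in 40 of 1335 of CTRL, with 53 and 43 nuclei left out, and unthinned in 54.4% and 6.89%. Inhibitory neurons, astrocytes and oligodendrocytes of Eed-cKO had one in 1.89%, 3.26% and 3.33% of thinned nuclei, with 45, 83 and 168 left out. A Cux2 UMI was in 6.64% of thinned Eed-cKO excitatory nuclei and 23.6% of those of CTRL, and unthinned in 21.9% and 60.4%. In Eed-cKO, oligodendrocytes had one in 6.67% of thinned nuclei, oligodendrocyte precursors in 16.8%, microglia in 4.35% (2.01 to 8.09) and astrocytes in 1.95% (0.721 to 4.21). The Eed-cKO excitatory share for Cux2 (interval 5.44 to 8.00) was thus above that of astrocytes but not above that of oligodendrocytes. These classes give no single background level.

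**Figure D3:**
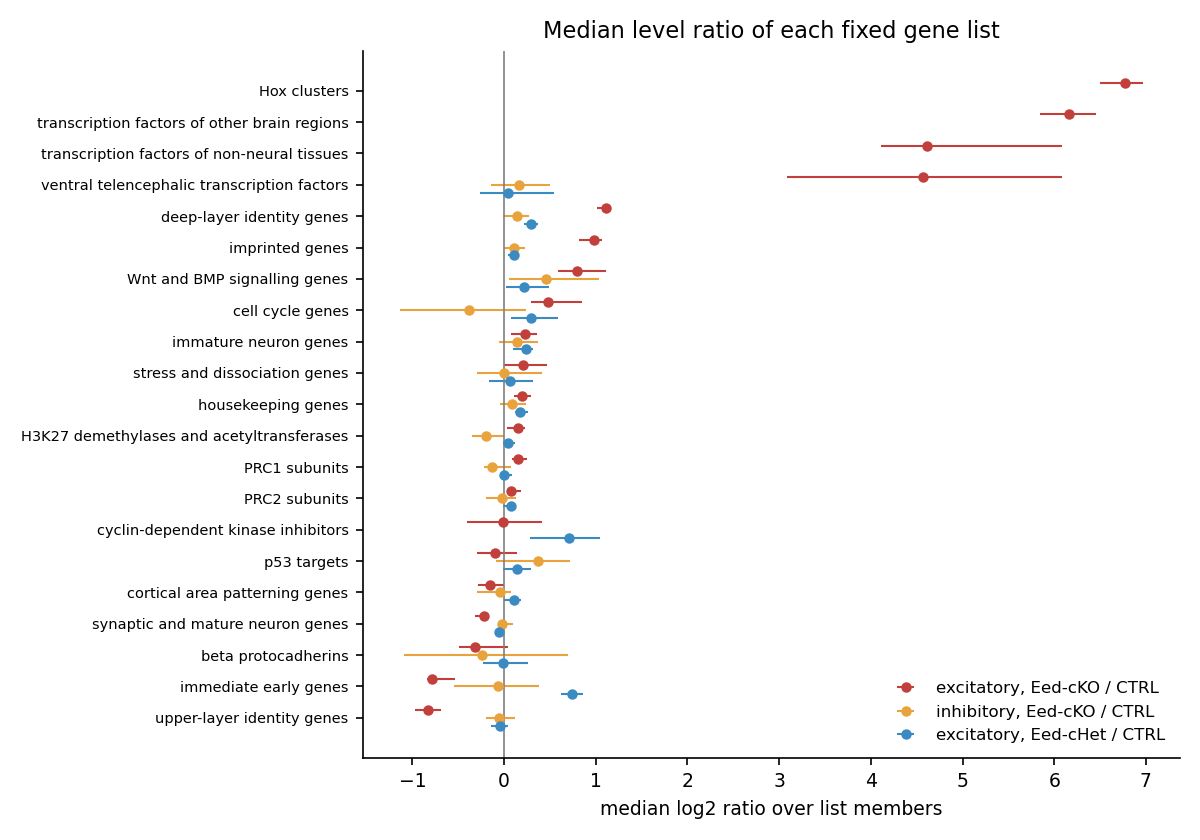
Median log2 ratio of the measured members of each fixed gene list in neurons, Eed-cKO over CTRL and Eed-cHet over CTRL, with 95% bootstrap intervals for counting error. In excitatory neurons of Eed-cKO the Hox list reaches 6.77, while upper-layer genes (-0.83) and immediate early genes (-0.79) lie below 0.

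Immediate early genes, which neurons switch on with activity, were lower in Eed-cKO and higher in Eed-cHet than in CTRL. In Eed-cKO 9 of 16 were at least 1.5-fold lower and 1 was higher (median log2 ratio -0.79, -0.84 to -0.53), with a summed level of 151 CPM against 252 CPM in CTRL. Arc, a synaptic plasticity gene, was at 34.9 CPM in CTRL, 52.6 CPM in Eed-cHet and 11.7 CPM in Eed-cKO (Eed-cKO over CTRL 0.336, 0.277 to 0.406). Egr1 was at 24.3, 41.9 and 14.0 CPM, and Ier2 had a ratio of 0.344 (0.180 to 0.629). Btg2 was higher (1.57, 1.07 to 2.32), while Nr4a3 (0.924, 0.735 to 1.16) was near CTRL. The excitatory neurons of CTRL, Eed-cHet and Eed-cKO also differed in mitochondrial UMIs (0.0210%, 0.0407% and 0.0607%) and in the nuclear RNA Malat1 (12.6%, 14.3% and 9.26% of UMIs), which can follow the handling of the nuclei.

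Imprinted genes, expressed from 1 parental copy, were higher in Eed-cKO, with 11 of 21 measured members at least 1.5-fold higher and none lower (median log2 ratio 0.98, 0.82 to 1.07). Nnat (ENSMUSG00000067786, chromosome 2, 157560078 to 157562522, inside Blcap), a membrane proteolipid gene of young neurons, was at 29.0 CPM in CTRL, 47.3 CPM in Eed-cHet and 228 CPM in Eed-cKO (ratio 7.88, 7.02 to 8.86). Dlk1, a Notch-like ligand gene, was at 0 in CTRL and 3.68 CPM in Eed-cKO, at least 13.8-fold higher. Snrpn, a splicing factor gene, was at 26.3 and 107 CPM (4.07, 3.59 to 4.63), and Peg10 had a ratio of 5.29. Igf2r (2.32) and Airn (2.36) overlap each other, so their UMIs cannot be assigned with certainty.

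Synaptic and mature neuron genes were slightly lower, with 5 of 25 lower and 1 higher (median log2 ratio -0.22, -0.32 to -0.17). Camk2a, a synaptic kinase gene, was at 929 CPM in CTRL and 478 CPM in Eed-cKO (0.515, 0.499 to 0.531), and Nrgn, a calmodulin-binding gene, at 175 and 86.5 CPM (0.493, 0.458 to 0.531). Gria1, a glutamate receptor gene, was higher (1.56, 1.51 to 1.61). Immature neuron genes went both ways, with 5 of 14 higher and 2 lower (median log2 ratio 0.23, 0.07 to 0.36). Gap43, of growing axons, was at 56.1 and 165 CPM (2.94, 2.69 to 3.22) and the tubulin gene Tubb2b had a ratio of 5.88 (2.48 to 16.9), while Nrep (0.352, 0.269 to 0.456) and Neurod2 (0.540, 0.458 to 0.635), a cortical neuron factor, were lower.

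Cortical area patterning genes also went both ways, with 6 of 17 higher and 5 lower (median log2 ratio -0.16, -0.29 to -0.0030). Nr2f2, a factor of caudal cortex, was at 1.51 and 14.0 CPM (ratio 9.22, with an upper bound of 16.2) and Etv1 had a ratio of 4.63 (3.99 to 5.38). Emx1, the dorsal telencephalic gene whose promoter drives the Cre, was at 10.4 CPM in CTRL and 3.91 CPM in Eed-cKO (0.375, 0.265 to 0.526), and Cdh6 was lower (0.478, 0.437 to 0.523). Wnt and BMP signalling genes had 6 of 12 measured members higher and 2 lower (median log2 ratio 0.80, 0.59 to 1.11). Lef1, the Wnt pathway factor, was at 0.624 and 7.36 CPM (11.8, 5.51 to 30.1) and Bmp6 had a ratio of 8.46 (3.67 to 24.0). Rspo1, a Wnt enhancer gene, was lower, at 19.8 CPM in CTRL and 1.07 CPM in Eed-cKO (0.0543, 0.0292 to 0.0930). It is also a fixed upper-layer subclass marker and a top gene of joint cluster 7, which held few Eed-cKO nuclei.

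Among the cyclin-dependent kinase inhibitors, Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653), a well known PRC2 target and brake on division, had 0 UMIs in CTRL, 4 in Eed-cHet and 36 in Eed-cKO, at least 10.3-fold higher. Cdkn1a was lower (0.623, 0.388 to 0.989), and the 4 measured members had a median log2 ratio of -0.016. Cell cycle genes had 3 of 8 higher (median log2 ratio 0.47, 0.30 to 0.85), with Cenpf at a ratio of 7.53 (3.62 to 18.1) and Mki67 at 1.29 (0.994 to 1.67). Polycomb genes differed little: 0 of 10 PRC2 subunits lay 1.5-fold apart (median 0.077, 0.034 to 0.18). For PRC1, 2 of 20 were higher and 2 lower (median 0.15, 0.09 to 0.25), with Pcgf2 at 0.602 (0.498 to 0.726). The H3K27 demethylases and acetyltransferases had 0 of 4 members 1.5-fold apart (median 0.16, 0.04 to 0.23).

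Of the other lists, beta protocadherins had 2 of 10 members higher and 2 lower (median log2 ratio -0.31, -0.50 to 0.04), and p53 targets 1 of 10 higher and 3 lower (-0.10, -0.30 to 0.14). Ccng1, a p53 target, had a ratio of 0.437 and Trp53inp1 a ratio of 1.66. Housekeeping genes had 3 of 22 higher and none lower (0.20, 0.11 to 0.29), with Eef1a1 at 1.71 and Actb at 1.01. Stress and dissociation genes had 2 of 8 higher and 1 lower (0.20, -0.01 to 0.47), with Jun at 2.68. The 2 sex-linked genes measured had a median of -0.026.

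Genes with the lowest ratios included Hs3st3a1, a heparan sulphate sulphotransferase gene (chromosome 11, 64435332 to 64522841), with 62 UMIs in CTRL and 1 in Eed-cKO (0.0139, 0.000346 to 0.0803). The non-coding gene Gm20752 was at 58.0 CPM in CTRL, 23.6 CPM in Eed-cHet and 3.45 CPM in Eed-cKO (0.0595, 0.0430 to 0.0805). Kcnab3, a potassium channel subunit gene, was at 11.9 and 0.460 CPM (0.0388, 0.0140 to 0.0868) and Cd200r1, an immune receptor gene, at 14.1 and 0.767 CPM (0.0545, 0.0256 to 0.103). Pttg1, the securin gene of cell division, had 39 UMIs in CTRL and 0 in Eed-cKO. Gm17167, 1700047F07Rik, 4933428C19Rik and Gm40331, of unknown function, had ratios between 0.0154 and 0.0690, and Gm17167 overlaps Gm13301. Gm20752, 1700047F07Rik, Gm40331 and Rspo1 were among the top genes of joint cluster 7. That cluster held 620 excitatory nuclei of CTRL and 22 of Eed-cKO. For these genes, a lower level in like nuclei cannot be told apart from the near absence of that cluster.

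Most excitatory nuclei of Eed-cKO lay in another joint cluster than those of CTRL and Eed-cHet. Joint cluster 6 held 956 excitatory nuclei of Eed-cKO (60.1%), 48 of Eed-cHet and 19 of CTRL, and joint cluster 7 held 22 of Eed-cKO, 831 of Eed-cHet and 620 of CTRL (45.0%). Hox genes summed to 172 CPM (163 to 182) in the Eed-cKO nuclei of cluster 6. In joint cluster 4, with 56 CTRL, 96 Eed-cHet and 250 Eed-cKO nuclei, they were at 70.2 CPM (59.5 to 82.2) in Eed-cKO and 0 in CTRL, which allows up to 7.68 CPM. There the transcription factors of non-neural tissues summed to 2.56 CPM in CTRL and 133 CPM in Eed-cKO, and those of other brain regions to 5.12 and 90.8 CPM. The layer genes went the other way in that cluster, with upper-layer genes at 875 and 1262 CPM and deep-layer genes at 8679 and 6361 CPM. In joint cluster 6 upper-layer genes were at 2246 CPM in CTRL and 2522 CPM in Eed-cKO, and deep-layer genes at 2793 and 2747 CPM. The layer differences over all excitatory nuclei were thus not seen inside either cluster. Clusters group nuclei by expression, and the deep-layer genes Hs3st4, Zfpm2 and Foxp2 were among the top genes of cluster 4. Its nuclei are therefore partly chosen on the genes compared, and cluster 6 held only 19 CTRL nuclei. These values cannot show whether like nuclei differ in layer genes. Joint cluster 19, with 204 nuclei of Eed-cKO, 41 of Eed-cHet and 1 of CTRL, had Hox genes at 1.10 CPM (0.133 to 3.96). Among excitatory nuclei, the upper-layer subclass was 44.2% in CTRL, 44.8% in Eed-cHet and 2.08% in Eed-cKO, while 50.7%, 48.8% and 92.4% could not be named. The layer 6 corticothalamic subclass was 3.99%, 5.12% and 2.77%, and the near-projecting subclass 1.16%, 1.32% and 2.77%. At resolution 0.5 the layer 6 corticothalamic subclass was 18.7% in Eed-cKO and 4.06% in CTRL. These subclasses are defined by layer genes that themselves differ, so no difference between genotypes is read from their sizes.

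**Figure D4:**
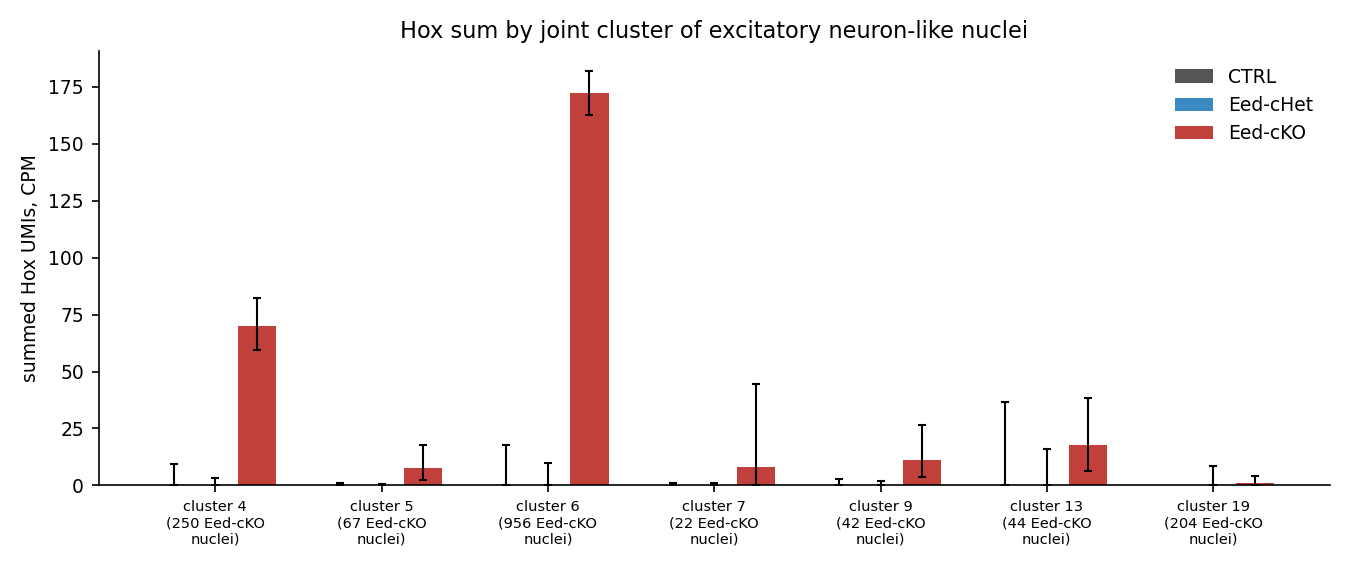
Summed Hox level (CPM) in the excitatory nuclei of each joint cluster for the 3 libraries, with exact Poisson 95% intervals and the number of nuclei under each bar group. In Eed-cKO the level is 172 CPM in cluster 6, 70.2 CPM in cluster 4 and 1.10 CPM in cluster 19.

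The comparison of Eed-cHet with CTRL asks how excitatory neurons differ between a library with 1 Eed copy deleted and the control library. Hox genes gave 1 UMI in Eed-cHet and none in CTRL, and no member of that list or of the transcription factors of other brain regions was measured. Immediate early genes were higher, with 14 of 16 at least 1.5-fold higher and none lower (median log2 ratio 0.74, 0.62 to 0.87), and a summed level of 411 against 252 CPM. Inhibitory neurons of Eed-cHet, given below, also had higher immediate early genes, so the difference was not confined to neurons of the Cre lineage. Its cause was not tested. Among these genes in excitatory neurons, Btg2 had a ratio of 3.49 (2.53 to 4.93), Junb 2.09, Egr3 1.91, Egr1 1.72, and Fos 1.72, with Arc at 52.6 CPM against 34.9 CPM, while Bdnf, a neurotrophin gene, was at 1.14.

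Deep-layer genes were higher in 5 of 17 measured members in Eed-cHet (median log2 ratio 0.29, 0.22 to 0.38), but in joint cluster 4 alone the median was -0.12. Rprm had a ratio of 2.45, Nr4a2 of 2.28, Syt6 of 1.88 and Foxp2 of 1.56. Upper-layer genes had 0 of 14 members 1.5-fold apart (-0.05). The other lists had medians between -0.059, for synaptic genes, and 0.71, for the 3 measured kinase inhibitors, of which Cdkn1b (1.87, 1.28 to 2.79) and Cdkn1a (1.64, 1.17 to 2.35) were higher. Imprinted genes had 2 of 18 members higher (0.11), with Ndn, a growth suppressor gene, at 5.24. The PRC2 subunits (0.07), PRC1 subunits (0.00) and H3K27 list (0.04) had no member 1.5-fold apart.

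Single genes in Eed-cHet excitatory neurons included Psat1 (ENSMUSG00000024640, chromosome 19, 15904678 to 15947337), of serine synthesis, at 1.16 CPM in CTRL, 19.2 CPM in Eed-cHet and 25.2 CPM in Eed-cKO (Eed-cHet over CTRL 16.5, 9.55 to 31.4). Gm8108 was at 0 in CTRL, 11.6 CPM in Eed-cHet and 7.90 CPM in Eed-cKO, at least 43.3-fold higher in Eed-cHet. Gm3453 was at 0, 2.40 and 3.76 CPM. It was also at least 4-fold apart between Eed-cKO and CTRL in microglia, which lie outside the Cre lineage. Gm5878, a lincRNA on chromosome 6 near Emx1, had 1, 56 and 60 UMIs (34.3, 5.91 to 1379). Gm21860, a Y-linked gene that overlaps Mid1-ps1, was at 0, 3.77 and 0 CPM, and its UMIs are of uncertain origin in a library that looks female. Lower genes were Col6a5, a collagen gene, at 5.97 and 0.273 CPM (0.0457, 0.0144 to 0.112), Gm20752 (0.407, 0.359 to 0.460), Vmn1r47, a pheromone receptor gene (0.134), Gm49164 (0.301) and 6530437J22Rik (0.388). 6530437J22Rik is antisense to Cpt1c, and Gm49164 was at 32.2 CPM in Eed-cKO against 5.08 CPM in CTRL.

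Inhibitory neurons, which arise outside the Cre lineage, were compared in the same way. The Eed-cKO library also held striatal-like nuclei, so this class may include inhibitory neurons from outside the cortex there, which was not tested. No Hox gene, transcription factor of other brain regions or transcription factor of non-neural tissues was measured there, and the Hox sum was 1.16 CPM (0.317 to 2.98) in Eed-cKO and 0 in CTRL. Of 9 ventral telencephalic factors 1, Dlx5, was higher (ratio 1.57, 0.702 to 3.98). Upper-layer genes had a median log2 ratio of -0.05, deep-layer genes 0.14, immediate early genes -0.06 and synaptic genes -0.02. Foxp2 was at 6.03 CPM in CTRL and 27.3 CPM in Eed-cKO (4.53, 2.29 to 10.2). After thinning, 1.89% of Eed-cKO inhibitory nuclei had a Foxp2 UMI, not above the 3.26% of astrocytes and 3.33% of oligodendrocytes. Free RNA as its source was not tested.

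Imprinted genes in inhibitory neurons had 4 of 19 members higher and 1 lower (median log2 ratio 0.11), with Nnat at a ratio of 2.59 (1.82 to 3.78), Ndn at 3.99 (1.59 to 12.9) and Snrpn at 1.59 (1.32 to 1.91). Wnt and BMP genes had 3 of 6 higher (0.46, 0.06 to 1.04), among them Dkk2, a Wnt inhibitor gene, at 0 in CTRL and 13.7 CPM in Eed-cKO, at least 6.80-fold higher, and Rspo3 (2.10, 1.15 to 4.17). Hmcn1, an extracellular matrix gene, was at 2.68 and 37.5 CPM (14.0, 5.34 to 52.1), and Tacr1, the substance P receptor gene, at 2.01 and 26.7 CPM (13.3, 4.41 to 65.7). Meis2, a homeobox gene of ventral forebrain neurons, was at 3.35 and 30.8 CPM (9.20, 3.82 to 28.9), and Rmst, a neurogenic lincRNA, at 1.34 and 16.9 CPM (12.6, 3.33 to 106).

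Lower in inhibitory neurons were Rnf121, a membrane ubiquitin ligase gene (ENSMUSG00000070426, chromosome 7, 102019137 to 102065469), at 168 CPM in CTRL and 38.3 CPM in Eed-cKO (0.228, 0.183 to 0.283). Syt2, a synaptic calcium sensor gene of fast-spiking neurons, was at 61.6 and 12.5 CPM (0.203, 0.138 to 0.294). Col16a1 had a ratio of 0.244, Gm32743 of 0.156 and 6330411D24Rik of 0.359. In Eed-cHet inhibitory neurons, immediate early genes were higher in 4 of 7 measured members (median log2 ratio 0.87, 0.37 to 1.27), with Nr4a3 at 2.43 (1.16 to 5.67), Junb at 2.34 and Fos at 2.03.

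Astrocytes of Eed-cKO, which the Cre lineage includes, had a Hox sum of 12.4 CPM (6.58 to 21.1) against 0 in CTRL, which allows up to 6.53 CPM. After thinning, 1.30% of them had a Hox UMI, against 0 of 118 astrocytes in CTRL and 0 of 440 in Eed-cHet. Unthinned it was 10 of 390, against 0 of 146 and 0 of 463. The thinned share was not above the 1.45% of Eed-cKO microglia, which lie outside the lineage. Microglia had Hox UMIs in each library, however, so their share is no measure of background in Eed-cKO. Spp1, the osteopontin gene, was at 0 and 47.6 CPM, at least 7.28-fold higher, and the myelin-associated factor gene St18 at 0 and 40.9 CPM, at least 6.26-fold higher. Gm29683 was at 0 and 59.9 CPM, at least 9.17-fold higher. Rnf121 was at 765 and 32.3 CPM (0.0423, 0.0288 to 0.0602), Cdh19, a cadherin gene, had a ratio of 0.325 and Dcc, the netrin receptor gene, a ratio of 0.388. Imprinted genes had 3 of 10 members at least 1.5-fold higher and 1 lower (median log2 ratio 0.31), with Nnat at 2.84 (1.97 to 4.24).

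In microglia of Eed-cKO, St18 had a ratio of 14.7 (3.82 to 126) from 2 UMIs in CTRL, Grik2, a kainate receptor gene, 6.65 and Ly6h 4.84. Trim12a (chromosome 7, 104299894 to 104315466) and Trim30d (chromosome 7, 104470014 to 104507849), antiviral TRIM family genes, each had 36 UMIs in CTRL and 0 in Eed-cKO, while Eed-cHet had 97.3 and 55.1 CPM. Adam2 had a ratio of 0.0945 (0.0243 to 0.266). In oligodendrocytes Tac1, the substance P precursor gene of striatal neurons, was at 3.52 and 36.1 CPM (10.2, 3.25 to 51.8), Mgat4c had a ratio of 6.70 and 1700042O10Rik, antisense to Ddc, of 4.56. Hcn2, a pacemaker channel gene, was at 139 and 22.8 CPM (0.164, 0.101 to 0.257), Lamp5 had a ratio of 0.162 and Zfhx4 of 0.273. Lamp5 was also lower in excitatory neurons of Eed-cKO, and free RNA of neurons as a source of these glial values was not tested. In oligodendrocyte precursors Nkain2 had a ratio of 3.66 (2.19 to 6.52), but a log2 ratio of -2.21 with each library clustered alone. Ostf1 had a ratio of 3.67 and 4732440D04Rik, antisense to Rb1cc1, of 7.86 (1.98 to 68.1), while Rnf121 (0.287), Grm8 (0.240) and the vessel growth factor gene Vegfa (0.430) were lower.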

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

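All tests of explanations in this part were chosen only after the result was seen, except the test of GABA genes in nuclei that lost Eed, which was written before.

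Striatal projection neuron-like nuclei were 11.9% of the Eed-cKO library and nearly absent from CTRL and Eed-cHet, in a class that the gene comparisons do not use. The share was between 6.63% and 6.82% with doublets kept, with no filter on nuclei and at resolution 2. Their Hox sum was 5.93% (3.71 to 9.01) of that in excitatory neurons of the same library, which goes with tissue from outside the dorsal cortex in the dissected piece. It was still above the Hox sum of inhibitory neurons of that library, which lie outside the lineage. Few nuclei carried it: unthinned, 7 of 512 striatal-like nuclei had a Hox UMI, against 4 of 574 inhibitory nuclei. Joint cluster 19 of the excitatory neurons, with 204 nuclei in Eed-cKO, 41 in Eed-cHet and 1 in CTRL, also had a low Hox sum of 1.10 CPM, but unlike the striatal-like class it was not confined to Eed-cKO. Nuclei of the Cre lineage that took a striatal fate cannot be told apart from this, because astrocytes, which the lineage forms, had a Hox sum of only 11.1% (lower bound 5.88) of that in excitatory neurons. Both the dissection and the genotype stay open with 1 library each, and shares of all other classes in Eed-cKO depend on the answer. Gene ratios of Eed-cKO inhibitory neurons may depend on it too, since inhibitory neurons from outside the cortex could fall in that class. The share of that class also moved, from 13.3% to 10.2% with doublets kept and 10.3% with no filter on nuclei.

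Gad1, Gad2 and Slc32a1, the genes of GABA neurons, were higher in excitatory neurons of Eed-cKO than of CTRL. Free RNA is argued against, since 11.5% (9.90 to 13.1) of thinned excitatory nuclei had a UMI of these genes, above the upper bound of 8.85% in oligodendrocytes of the same library. Oligodendrocyte precursors, left out of that test, had 7.69% (3.90 to 13.3) in Eed-cKO, which overlaps the excitatory interval, and 9.76% in CTRL. Doublets or misplaced inhibitory neurons would need 11.6% of inhibitory RNA, but 11 other markers gave a median of 4.05% (1.15 to 5.12), and for striatal-like nuclei 18.1% was needed against 5.09% (1.05 to 5.57) over 7 markers. Expression in nuclei that lost Eed stays open: the genes had a UMI in 16.8% (upper bound 22.6) of thinned nuclei with a Hox UMI and in 10.6% (upper bound 12.4) of those without, and the intervals of these 2 shares overlap. A mixture of sources, each giving part of the UMIs, was not tested.

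Some genes differed between Eed-cKO and CTRL in classes outside the Cre lineage. Trim12a and Trim30d had no UMI in Eed-cKO microglia, and Rnf121 was lower in inhibitory neurons with a ratio of 0.228 (0.183 to 0.283). Rnf121 was chosen for its low ratio in inhibitory neurons, so the test of deletion in that class had a fixed outcome and decides nothing. Rnf121 was also lower in microglia, where it was not among the genes picked. Inhibitory neurons and microglia lie outside the lineage, so the lower level was not confined to it, but a part of the deletion in classes of the lineage was not tested. Rnf121 lies on the same chromosome as Eed and within 20 Mb of it. Linked DNA of another mouse strain around Eed stays open: 1.87% (0.227 to 6.59) of 107 microglial genes within 20 Mb of Eed were at least 4-fold apart, against 0.293% of 6150 genes elsewhere, and 2 genes are too few to decide. No biological explanation was tested for these genes beyond the deletion.

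Other differences between classes were not tested. H3K27 demethylases and acetyltransferases had a median log2 ratio, Eed-cKO over CTRL, of 0.16 in excitatory neurons, -0.29 in astrocytes and -0.20 in inhibitory neurons. Upper-layer identity genes had a median of -0.83 in excitatory neurons and 0.55 in oligodendrocyte precursors, over 5 members such as Cux1 and Cux2. Cortical area patterning genes had a median of -0.16 in excitatory neurons and 0.60 in microglia or macrophages, over 3 members such as Etv1 and Lmo4. In Eed-cHet over CTRL, synaptic and mature neuron genes had a median of 0.42 in astrocytes and -0.059 in excitatory neurons.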

How the results depend on the processing

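The alternatives limited to joint cluster 4, to nuclei with no UMI of Gad1, Gad2 or Slc32a1 and to nuclei outside joint cluster 19 were chosen after seeing the data. No paired analysis was possible because each genotype is 1 library and the labels share no replicate numbers. Leaving out a library or regrouping libraries was not possible for the same reason.

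Of 143 list medians under the alternatives, 86 stayed within their interval, 54 moved with the same direction and 3 reversed. The Hox, other brain region and non-neural lists, whose direction the UMI minimum fixes, nearly fixes and favours, stayed higher in Eed-cKO in every alternative that gave a value, with medians of up to 8.34, 6.51 and 8.27, and the Hox median was never under 4.81. Immediate early genes stayed lower in Eed-cKO (-1.44 to -0.61) and higher in Eed-cHet (0.66 to 0.82), and imprinted genes stayed higher in Eed-cKO (0.42 to 1.15). Of 613 values for single genes, 519 stayed, 91 moved and 3 reversed. In joint cluster 4, where nuclei of each library are compared within 1 cluster, the deep-layer median was -0.43 in Eed-cKO and -0.12 in Eed-cHet, and the upper-layer median 0.69 in Eed-cKO, each reversed. When excitatory nuclei were clustered again, a subcluster scoring highest for layer 6 corticothalamic held 55 CTRL and 44 Eed-cKO nuclei. Another such subcluster held 1 and 259, so the CTRL and Eed-cKO nuclei of joint cluster 4 may be unlike. Nkain2 in oligodendrocyte precursors reversed to -2.21 with each library clustered alone. The cause was not tested. Cd200r1 (0.69) and Gm5878 (-0.015, Eed-cHet) also had the other sign in joint cluster 4, from 4 and 1 UMIs against 0 in CTRL, so the prior sets these values and no direction can be read. The Hox list had no member with enough UMIs in that cluster.

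Counts of higher members were lower where fewer members passed the UMI minimum. With 100 UMIs the Hox, other brain region and non-neural lists each had 3 higher members and the ventral list 2. Thinned, the Hox list had 3, the other brain region list 1, the non-neural list 3 and the ventral list 1. With no UMI of Gad1, Gad2 or Slc32a1 they had 6, 8, 8 and 2. In joint cluster 4 alone the other brain region list had 1, the non-neural list 2 and the ventral list 1. With 10 UMIs more members passed, and the other brain region list had 25, the non-neural list 34 and the ventral list 13.

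In joint cluster 4 the Eed-cKO deep-layer list had 2 of 16 members higher, the imprinted list 7 of 16 higher, the upper-layer list 0 of 11 lower and the immediate early list 4 of 4 lower, and the cause was not tested. Against Eed-cHet, 16 immediate early genes were lower in Eed-cKO. For Eed-cHet, higher immediate early genes numbered 9 thinned and 5 in joint cluster 4. Higher deep-layer genes numbered 3 with 100 UMIs, 2 thinned, 3 with a mean over nuclei, 1 in joint cluster 4 and 3 with the subclass composition fixed, and the cause was not tested. In inhibitory neurons of Eed-cHet, 1 immediate early gene was higher with 100 UMIs and 7 with a mean over nuclei.

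Of 80 shares, 45 stayed within their interval and 35 moved, and the cause was not tested except where given. With at least 1000 genes per nucleus, excitatory neurons were 64.3% in CTRL, 51.4% in Eed-cHet and 45.1% in Eed-cKO, and inhibitory neurons 10.9%, 8.97% and 15.4%. Excitatory neurons of CTRL, Eed-cHet and Eed-cKO were 38.5%, 32.0% and 36.6% at resolution 2 and 36.6%, 30.8% and 36.8% with each library clustered alone. Under both, the smaller shares came with clusters left unnamed although they scored highest for excitatory neurons. With these added, a step chosen after seeing the data, the shares were 50.5%, 40.7% and 37.4% at resolution 2 and 50.6%, 40.6% and 36.8% clustered alone. Inhibitory neurons of CTRL, Eed-cHet and Eed-cKO were 7.19%, 6.02% and 10.2% with doublets kept, 7.07%, 5.91% and 10.3% with no filter on nuclei, and 7.32%, 6.34% and 10.5% centred per library. With each library clustered alone, inhibitory neurons of Eed-cKO were 10.5%. Striatal-like nuclei of Eed-cKO were 6.76% with doublets kept, 6.63% with no filter, 6.82% at resolution 2 and 10.8% with each library clustered alone.

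At resolution 0.5 the upper-layer subclass was 81.1% of excitatory nuclei in CTRL, 78.2% in Eed-cHet and 5.53% in Eed-cKO, and unnamed nuclei 13.7%, 15.4% and 73.0%. Centred per library, Eed-cHet had 41.9% upper-layer and 51.6% unnamed nuclei, and Eed-cKO 75.8% unnamed. The layer 6 corticothalamic subclass of Eed-cKO was 18.7% at resolution 0.5 and 18.6% centred per library, against 4.06% in CTRL under both. At the depth here, no Hox gene reached 30 UMIs over CTRL and Eed-cKO in any of the 6 classes but excitatory neurons, so no ratio could be given there.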

Other observations

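The imprinted genes were higher in Eed-cKO inside joint cluster 4 as well, with a sum of 10466 CPM in CTRL and 17115 CPM in Eed-cKO. Immediate early genes there summed to 259 and 105 CPM. In the Eed-cKO nuclei of joint cluster 6, transcription factors of other brain regions summed to 143 CPM and those of non-neural tissues to 171 CPM, against 14.5 CPM for each list in the 19 CTRL nuclei there. Gad1, Gad2 and Slc32a1 summed to 116 CPM in the Eed-cKO nuclei of cluster 6 and to 49.1 CPM in those of cluster 4.

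Rnf121 was lower in Eed-cKO than in CTRL in each of the 6 classes compared, with ratios of 0.0423 in astrocytes, 0.228 in inhibitory neurons, 0.267 in excitatory neurons, 0.287 in oligodendrocyte precursors, 0.358 in oligodendrocytes and 0.432 in microglia. Striatal RNAs were found in glia of Eed-cKO, where Penk was at 33.2 CPM in oligodendrocytes and 51.8 CPM in microglia, against 4.70 and 11.7 CPM in CTRL. Tac1 was at 28.5 CPM in Eed-cKO astrocytes and 0 in CTRL, and the striatal-like nuclei themselves held Penk at 182 CPM and Tac1 at 127 CPM.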
